A study of Daphnia magna with 15 samples.

How the data were processed

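Genomic DNA of adult female Daphnia magna was profiled in 15 bisulfite libraries, 3 labelled control and 12 labelled salinity. Per the labels' protocols, DNA was digested with MspI, ligated to methylated adapters and converted with bisulfite. Per the submitters' processing notes, Trim Galore 0.4.4, FastQC and Bismark 0.18.1 were used. The genome build, the cytosine context, the rule for calling a position methylated and the way positions were summed per gene model are not given in the sources used here.

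The authors deposited 1 table per library with a line for each mRNA gene model, a position, and 2 counts named N and X in the file headers. N was read as the total count of cytosine calls and X as the count of methylated calls, because X was never above N. Both are raw counts without normalization, as deposited by the authors. The methylated values were deposited as numbers that need not be whole and were handled like estimated counts, because 27 of them missed a whole number by up to 1e-14, and they were rounded to whole numbers. The word call is used for a unit of these counts. Methylated counts of 1 and 2 are nearly missing from the deposited counts, so small numbers of methylated calls appear as 0. No upper limit was therefore derived from a count of 0, and the lowest recurring methylated count of a library was taken as the lowest value that made up at least 5% of its methylated gene models.

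No 2 libraries held identical tables (0 pairs). Some 700 gene models had 2 different positions across libraries and were joined by identifier, and 649 gene models in 295 groups had identical counts in every library. Of the 25092 identifiers, 0 matched the 28335 genes of the reference table, so gene names were not used and the gene lists fixed beforehand (ion transport, chaperones, the DNA methylation machinery and others) could not be tested. No genome was used, and no position is reported.

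The groups were taken from the treatment label. The labels hold no replicate numbers. Those used here were given in the order of the samples, only name libraries and pair nothing. Levels were computed over gene models with at least 10 calls in every library, as methylated calls over all calls, as the mean of the gene models' levels, and as the share of gene models at 50% or more. The share of gene models with any methylated call was added after the data were seen. Group means of these values and of the number of listed gene models were compared with a two-sided exact permutation test over all 455 splits of 15 libraries into 3 and 12, whose smallest possible p is 0.00220. Intervals of the difference were made by inverting that test at the 95% level, and Wilson intervals at 95% were computed for the level of single libraries. They cover counting error only.

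Gene models with at least 10 calls in at least 2 control and 8 salinity libraries were tested with a quasi-binomial logistic regression on methylated and total calls. The two-sided F test on the deviance used a Pearson dispersion floored at 1, with Benjamini-Hochberg adjustment at 0.05. The regression was computed in closed form for the comparison of 2 groups. It was tested on simulated data for 1900 gene models with 50 changed in each direction at 10 and at 30 percentage points, where 10 of 1700 unchanged gene models were called. With no change anywhere, 2.74% of the simulated gene models had an unadjusted p under 0.05. In both simulations unchanged gene models without methylated calls (1381 of the 1900 in the data) stayed at 0 and could not be called. The 52 with a p under 0.05 thus came from the 519 others, which is above a share of 0.05. The simulated counts had no lowest methylated count and an assumed spread between libraries, and drops were made by raising the controls. The gene models named follow a rule fixed beforehand, namely those that pass or, if fewer than 10 pass, the 10 with the smallest p, and the 5 with the highest mean level. As identifiers could not be paired with names, the text prints only a few of them. The counts of recurrently methylated gene models, the 100 shuffles of methylated state within libraries and the levels over these gene models were added after the data were seen. Correlations were tested with 100000 permutations.

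The settings varied, as fixed before the data were examined, were coverage minimums of 5 and 20, leaving out each library in turn for the levels and the gene model tests, the gene models covered in each library, the bands of title numbers as a block, levels of 10% and 80%, edgeR's quasi-likelihood test, limma on logit levels with 0.5 added to the counts, Fisher's exact test on pooled counts, a dispersion without floor, and a minimum difference of 10 percentage points. Settings chosen after seeing the data concern the lowest methylated count, salinity replicates 11 and 12 (both also over the gene models common to all libraries), leaving out libraries for the number of listed gene models, gene models at 2 positions or with identical counts, the 50 common gene models with most calls, gene models with any methylated call, and every listed gene model. A first choice of the 50 gene models with most calls overall removed no tested gene model and was replaced. The planned correlations with depth over 15 libraries and over the 12 salinity libraries were replaced, because the levels fell into clusters. They were run over the 11 libraries with a lowest count of 3 and over the 9 salinity libraries among them. The analysis of mRNAs is the analysis of single features, since the files list mRNAs.

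Total depth ran from 1250901 to 2905380 calls per library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 with edgeR 4.0.16 and limma 3.58.1 were used.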

Results

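DNA methylation was measured in adult females of Daphnia magna, a freshwater crustacean (water flea) used as a test animal in aquatic toxicology. Founder cultures were kept either without added sodium chloride or at 4.1 g/L NaCl, at 20 °C with 16 h of light and 8 h of darkness. The labels describe 6 founding cultures, 3 for each exposure, with later generations started from newborns and kept in control medium up to generation 4. There were 15 libraries, 3 labelled control and 12 labelled salinity. The generation of each salinity library was not in the labels, so the 12 were compared with the 3 controls as a single group.

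Each library was genomic DNA cut with MspI, a restriction enzyme that cuts at CCGG, and converted with bisulfite, which turns unmethylated cytosines into bases read as thymine. For every gene model (mRNA) that a library listed, the deposited values gave the total number of cytosine calls and the number of methylated calls. The methylation level of a gene model was the second divided by the first. The 15 libraries listed 25092 gene models between them. Single libraries listed from 8053 gene models (salinity replicate 12) to 18896 (salinity replicate 8), and held 1250901 to 2905380 calls. The median depth ranged from 45 calls per gene model in salinity replicate 12 to 75 in salinity replicate 2. The 50 gene models with most calls took 4.82% of the calls in control replicate 1 and 20.0% in salinity replicate 11, the lowest and highest of the 15 libraries.

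Methylation was sparse and sat in a small part of the gene models. Among 191026 listings of a gene model in a library, 14690 (7.69%) carried any methylated call. Where methylated calls were present, the median level was 6.33%, the 90th percentile 30.8% and the 99th percentile 77.8%, and 95 listings were at 100%. Methylated counts of 1 and 2 were almost missing, with 2 and 6 listings, against 4530 listings with a count of 3 and 3722 with a count of 4. The lowest recurring methylated count was 3 in 11 libraries and 4 in control replicate 3 and salinity replicates 9, 11 and 12. A level of 0 therefore stands for few methylated calls or none.

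**Figure D1:**
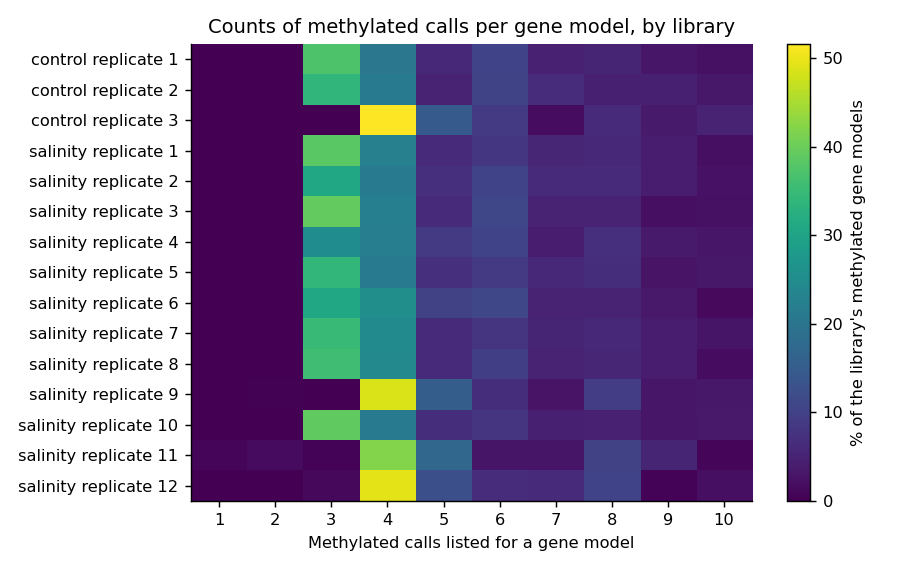
Methylated calls listed per gene model (x axis, counts from 1 to 10) in each of the 15 libraries (y axis), as the percentage of the library's gene models with methylated calls (colour). A count of 3 made up 37.1% of them in control replicate 1 and 34.0% in control replicate 2, but 0 in control replicate 3 and salinity replicate 9, 0.488% in salinity replicate 11 and 1.10% in salinity replicate 12.

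Gene models were present or missing in blocks shared by sets of libraries. Only 1387 gene models were listed in every library, and 810 of them had at least 10 calls in every library. The 25092 gene models fell into 987 patterns of listing libraries, and 54 patterns of 20 or more gene models held 23130 of them (92.2%). The largest pattern held 2938 gene models listed in the same 7 libraries.

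**Figure D2:**
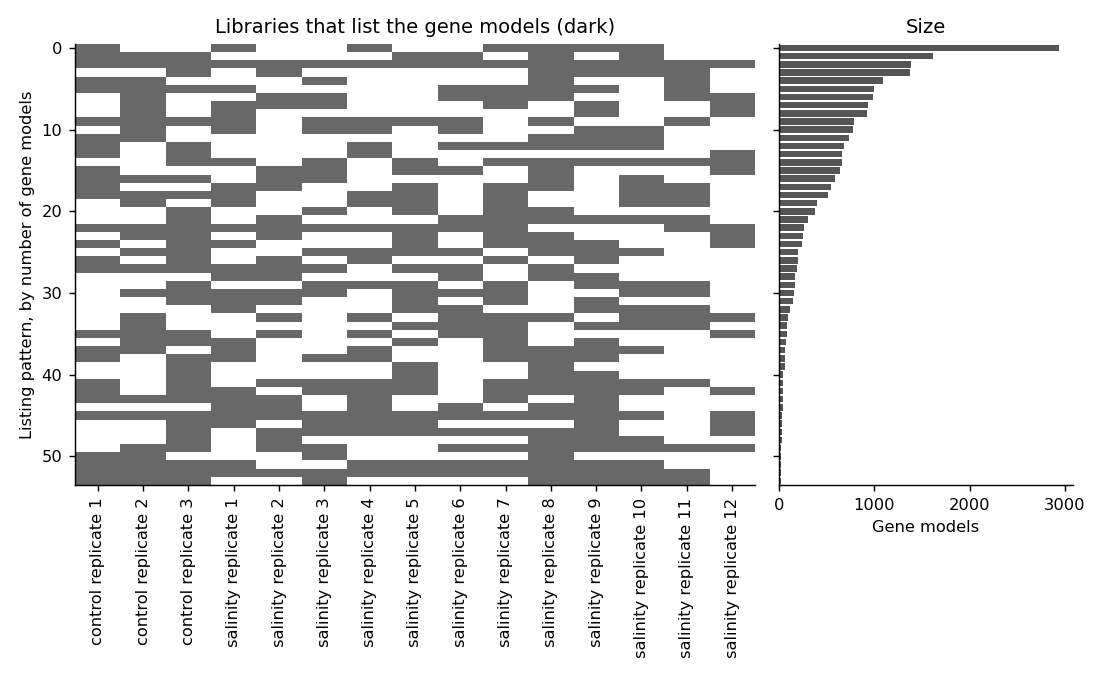
Patterns of libraries that list the same gene models, for the 54 patterns with 20 or more gene models. Each line on the left is a pattern, dark where the library on the x axis listed its gene models, and the bar on the right gives the number of gene models, up to 2938.

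The main question of the series was whether DNA methylation differed between exposed and non-exposed daphnids. Libraries labelled salinity may come from founders kept at 4.1 g/L NaCl or from their descendants in control medium, so the comparison is one of labels, with exposure of the animals or of their ancestors. Over the 810 gene models read at 10 or more calls in every library, 0.220% ± 0.0694 (SD, n = 3) of calls were methylated in the control group and 0.233% ± 0.0519 (SD, n = 12) in the salinity group. The difference of 0.0130 percentage points was smaller than the spread between libraries of either group (two-sided exact permutation test over all 455 splits, p = 0.747). The interval of differences that the test did not reject at the 95% level ran from -0.0635 to 0.0884 percentage points, which is -28.8% to 40.1% of the control mean. These gene models held 3.59% to 8.38% of a library's calls, with 155 to 428 methylated calls per library. Without control replicate 3 the salinity mean was the lower one, with a difference of -0.0263 percentage points (exact permutation p = 0.505).

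The single libraries overlapped between the groups. The 2 controls with a lowest count of 3 were at 0.256% and 0.264%, within the range of 0.209% to 0.312% in the 9 salinity libraries with that lowest count. Control replicate 3 was at 0.140%, and the 3 salinity libraries with a lowest count of 4 ran from 0.139% to 0.248%. Over the 810 gene models these 11 libraries had means of 0.260% in control and 0.251% in salinity (exact permutation over 55 splits, p = 0.782). Over the gene models covered in each of them the means were 0.355% and 0.324% (p = 0.200 in the same exact permutation), and over the 938 gene models covered in all 11 they were 0.278% and 0.302% (exact permutation p = 0.564), so the direction depended on the gene models taken. The sample titles carry numbers in 3 bands, 1 to 5, 10 to 14 and 17 to 21, each with 1 control and 4 salinity libraries. Within the bands the control was at 0.256%, 0.264% and 0.140%, and the salinity mean at 0.245% ± 0.0459, 0.226% ± 0.0668 and 0.228% ± 0.0549 (SD, n = 4). The difference thus went down in the first 2 bands (-0.0106 and -0.0385 percentage points) and up in the third (0.0881). With permutation within bands the exact p was 0.76 over 125 splits.

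**Figure D3:**
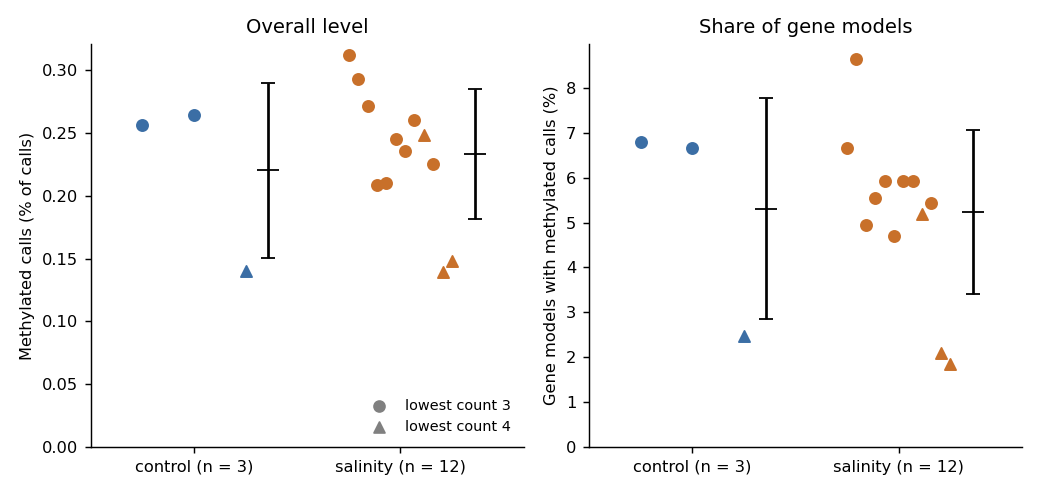
Overall methylation level (left, % of calls) and share of gene models with any methylated call (right, %) in each library over the 810 common gene models. Symbols are single libraries by their lowest recurring methylated count (circles 3, triangles 4), and the bars are the group mean ± SD (control n = 3, salinity n = 12). The lowest levels in both groups, 0.140% in control and 0.139% in salinity, belong to libraries with a lowest count of 4.

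The groups also overlapped when each gene model had the same weight. The mean level of the 810 gene models was 0.414% ± 0.235 (SD, n = 3) in control and 0.442% ± 0.142 (SD, n = 12) in salinity libraries (two-sided exact permutation p = 0.820). Without control replicate 3 the difference in mean level turned from 0.0276 to -0.106 percentage points, so that library set its direction. Methylated calls occurred in 5.31% ± 2.46 (SD, n = 3) of these gene models in control and 5.24% ± 1.83 (SD, n = 12) in salinity libraries (exact permutation p = 0.980), with an interval of the difference from -2.84 to 2.72 percentage points and leave-one-out differences from -1.45 to 0.668. A level of 50% or more was found in 1 of the 810 gene models in control replicate 1 and in none in the 14 other libraries, where the exact permutation p of 0.200 follows from a single library above 0. Over the gene models covered in each library, this share was 0.179% ± 0.0978 (SD, n = 3) in control and 0.162% ± 0.0728 (SD, n = 12) in salinity (exact permutation p = 0.710). Over all listed gene models of a library, the level was 0.357%, 0.368% and 0.155% in control replicates 1 to 3. It ran from 0.106% (Wilson 95% interval 0.100% to 0.111%) in salinity replicate 12 to 0.384% (0.375% to 0.393%) in salinity replicate 5. These intervals cover counting error only, since calls on the same read are not independent.

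Single gene models were compared to find loci where exposure went with higher or lower methylation. No gene model of the 1900 with enough calls passed the test (quasi-binomial regression, two-sided F test, Benjamini-Hochberg adjusted p under 0.05), and the smallest adjusted p was 0.220. At an unadjusted p under 0.05 there were 57, of which 51 had the lower mean in salinity and 6 the higher. Limma on logit levels of the same 1900 gene models also called 0, with 72 at an unadjusted p under 0.05 (41 lower and 31 higher in salinity). The edgeR quasi-likelihood test, on the 519 with any methylated call, called 0, with 17 (11 lower and 6 higher). With the title bands as a block there were 76 (54 lower and 22 higher) and 0 calls, so the excess of lower means depended on the test. Of the 1900 gene models, 1381 (72.7%) had no methylated call in any library with sufficient coverage.

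The 10 gene models with the smallest p all had the lower mean in salinity, with 0 methylated calls in every covered salinity library and control means of 0.254% to 15.8%. Their adjusted p ran from 0.220 to 0.371, so none passed, and in 9 of the 10 the methylated calls came from 1 control library. The files do not pair the gene model identifiers with gene names. The exception with methylated calls in 2 controls was Dapma7bEVm003477t1, with 17 methylated of 801 calls in control and 0 of 1121 in salinity libraries. Its level was 1.98% ± 1.79 (SD, n = 3) in control and 0 in all 8 covered salinity libraries (adjusted p = 0.220; exact permutation of the levels, p = 0.0545). On simulated changes in the same 1900 gene models, the regression recovered 70% of drops and 20% of rises of 10 percentage points, and 96% and 82% for 30 percentage points. The simulated counts had no lowest methylated count and an assumed spread between libraries, and drops were made by raising the controls. These shares therefore need not hold for the deposited counts.

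The 5 tested gene models with the highest mean level were methylated in both groups, though Dapma7bEVm006915t1 in only 1 of 3 controls. They rested on few calls, 38 to 119 over the covered controls. Over all libraries they averaged 16.0% to 30.2%, with 4 of the 5 lower in salinity by mean and exact permutation p from 0.35 to 1. The highest, Dapma7bEVm005411t1, was at 33.7% ± 19.4 (SD, n = 2; 44 calls) in control and 29.3% ± 23.7 (SD, n = 8; 128 calls) in salinity libraries (exact permutation p = 0.889).

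Methylation recurred at the same gene models across libraries and groups. Of the tested gene models, 59 were methylated in at least 50% of the libraries that covered them, against at most 2 in 100 shuffles that kept each library's number of methylated gene models within 5 coverage classes. At least 80% of the covering libraries were methylated at 8 gene models, against 0 in every shuffle. Of 60 gene models methylated in at least 2 controls, 59 (98.3%) were also methylated in at least 1 salinity library, against a median of 51.1% and at most 80% in the same shuffles, and the exception was again Dapma7bEVm003477t1. In at least 50% of the covering salinity libraries, 23 of the 60 (38.3%) were methylated, against 0 in the shuffles, and of the 61 gene models methylated that often in salinity, 12 were methylated in no control. The mean level per library over those of the 59 recurrent gene models that it covered, 36 to 59 of them, was 7.72% ± 3.05 (SD, n = 3) in control and 7.86% ± 2.05 (SD, n = 12) in salinity (exact permutation p = 0.936). Over the 17 of them covered in every library it was 7.10% ± 3.67 (SD, n = 3) and 8.25% ± 2.91 (SD, n = 12), with an exact permutation p of 0.571. In the 11 libraries with a lowest count of 3, over the covered ones, it was 9.47% ± 0.476 (SD, n = 2) in control and 8.63% ± 1.63 (SD, n = 9) in salinity, in the other direction (exact permutation p = 0.418). Of the 59, 31 had the higher and 28 the lower mean in salinity, and 0 passed (smallest adjusted p 0.564, 5 at an unadjusted p under 0.05). These 59 were picked over all libraries, in which the salinity libraries outnumber the controls.

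**Figure D4:**
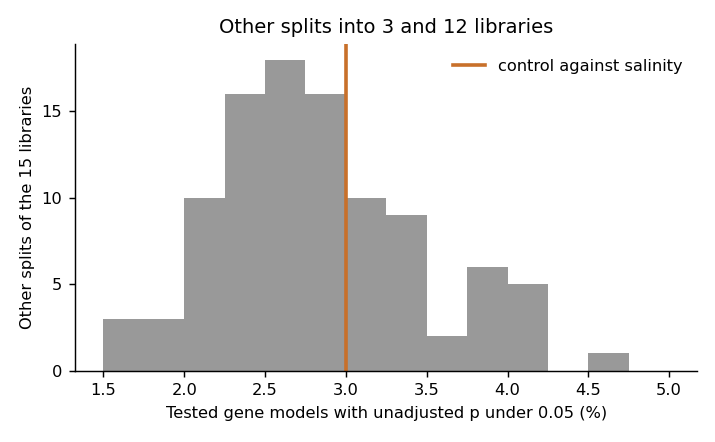
Share of the tested gene models with an unadjusted p under 0.05 (x axis, %) in 99 other splits of the 15 libraries into 3 and 12 (grey bars, y axis the number of splits) and in control against salinity (orange line, 3.00%). The other splits, which tested 1520 to 3067 gene models, ran from 1.58% to 4.55%, with a median of 2.72%.

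The number of gene models listed was lower on average in the salinity libraries, within the spread of that group. Control libraries listed 14694 ± 1079 (SD, n = 3) and salinity libraries 12245 ± 3060 (SD, n = 12), a difference of -2448 (two-sided exact permutation p = 0.207). The methylation level over the 810 common gene models was also compared with depth, in the 11 libraries with a lowest count of 3. Control replicate 3 and salinity replicates 11 and 12 lay below these 11. Salinity replicate 9, which was also left out, lay within their range (0.248%). Salinity replicate 12 had the fewest calls of all libraries (1250901) and a level of 0.148%. The planned relation over all 15 libraries is not reported, so the values that follow describe the 11 only. The overall level and the total calls had a Pearson r of 0.0762 (permutation p = 0.823) and a Spearman rho of 0.136 (permutation p = 0.694). Without the 2 libraries farthest from the median depth r was 0.196. It was the first of 4 such relations, with Benjamini-Hochberg adjusted p of 0.910 for r and 0.924 for rho.

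The labels do not tie single libraries to cultures, and 12 salinity libraries from 3 exposed cultures cannot all be independent exposures. The p-values measure the spread between these libraries, part of which may be technical or shared within a culture.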

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

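The settings around the lowest methylated count, around salinity replicates 11 and 12, around doubled, most-called or all listed gene models, all settings for the share of gene models with methylated calls, and leaving out libraries for the number of listed gene models, were chosen after the data were seen. No difference in level or number of listed gene models passed under any setting tried. The difference in overall level, 0.0130 percentage points, turned to -0.0102 over the gene models covered in each library and to -0.00977 over every listed gene model, and in the 11 libraries with a lowest count of 3 to -0.00875 over the 810 common gene models and -0.0311 over those covered in each library. That in mean level, 0.0276, turned to -0.0346, -0.0234, -0.0585 and -0.111 in these settings. The difference in the share at 50% or more, -0.0412, was 0.0412 at a level of 10%. The share with methylated calls, -0.0720, turned to 0.0796 at a minimum of 5 calls, 0.123 with counts of 3 set to 0, 0.973 without salinity replicates 11 and 12, and 0.580 without them over the 810 gene models. Without these 2 libraries the difference in overall level was 0.0617 (exact permutation p = 0.0979) and that in mean level 0.192 (exact permutation p = 0.0664, the lowest of any level test). Leaving libraries out also changes which gene models all the others cover, and over the 810 these values were 0.0309 and 0.0774. The causes were not tested.

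Leaving out 1 library at a time, the overall difference ran from -0.0263 (without control replicate 3) to 0.0357, that in mean level from -0.106 (without the same library) to 0.120, that at 50% or more from -0.0613 to 0, and that in the share with methylated calls from -1.45 (again without it) to 0.668. The last was also above 0 without control 2 or salinity 11 or 12. The difference in listed gene models ran from -3053 to -1894. The count of gene models that passed ran from 0 to 0, with a smallest adjusted p of 0.0595 to 0.445. The labels give no replicate numbers, and the block of title bands gave 0 calls.

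No gene model passed in the main test, but 23 (all lower in salinity) passed with the dispersion not floored. With Fisher's exact test on pooled counts, which ignores the spread between libraries, 41 passed (30 lower, 11 higher). Of the 41, 28 had methylated calls in at most 1 control, which for those higher in salinity is part of the difference itself. In 16 of the 41, at most 1 library of each group had methylated calls. With counts of 3 set to 0, 2 passed, Dapma7bEVm004532t1 (2.11% in control, 0 in salinity) and Dapma7bEVm015122t1 (1.72% and 0), named after their values were seen, both with adjusted p = 0.0344. This removed the calls of the 1 methylated salinity library in each; as deposited their adjusted p was 0.517 and 0.484. The smallest adjusted p ran from 4.61e-05 to 0.763 over all settings. The gene lists were not run for lack of names.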

Other observations

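All tests in this part were chosen after the result they bear on was seen, apart from the counts over other splits of the libraries, which were planned but whose outcome was seen before a prediction was written, and of which the share of tested gene models was added later.

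Control replicate 3 and salinity replicates 9, 11 and 12 had the lowest shares of methylated calls over all their gene models, 0.155%, 0.190%, 0.124% and 0.106%, and a lowest methylated count of 4 in place of 3. A count of 4 or 5 passes both lowest counts. With a lowest count per position, a gene model with positions of 4 and 3 would be listed with 4 under the stricter one. The stricter one could thus raise the share with 4 or 5, but not lower it. Counts of 4 or 5 were found in 2.46% of gene models in control replicate 3 and 3.26% in salinity replicate 9. In the 11 other libraries the share was 1.99% to 3.14%. In salinity replicate 9 the share with 4 or more (5.09%) lay within the 4.21% to 7.32% of those 11. A stricter lowest count thus stays possible for that library. Its level over the 810 common gene models cannot decide this, because it lay within the 11 already as deposited. With counts of 3 set to 0 in every library it was 0.248%, against 0.164% to 0.262% in the 11. Its level over all gene models, which was the low one, was not recomputed that way. For control replicate 3 the question stays open. Its level over the 810 with counts of 3 set to 0 (0.140%) and its share with 4 or more (3.72%) lay below all 11. A lowest count applied per position before summing could leave sums of counts of 3 in the 11, which would raise both. The listed counts go with such a rule. In each of the 11 a count of 6 was more frequent than 5 (157 against 89 gene models in control replicate 1). In the libraries with a lowest count of 4, a count of 8 was more frequent than 7 (31 against 9 in control replicate 3). Setting counts of 3 to 0 then does not make the libraries alike, so neither value can decide the question. In salinity replicates 11 and 12 the share with 4 or 5 was 1.11% and 1.40%, below all 11, which argues against the lowest count as the whole cause there. It stayed at 1.16% and 1.45% after reweighting to the same calls per gene model (2.00% to 3.10% in the others), and over shared gene models it was lower in 22 of 22 pairs, which argues against fewer calls and other gene models. Control replicate 3 and salinity replicates 9 and 12 belong to the title band 17 to 21, and salinity replicate 11 to 10 to 14. Salinity replicates 3 and 6 of the band 17 to 21 had a lowest count of 3. The title band, a calling rule that differed in another way, conversion, and the treatment or the generation of these libraries were not tested and stay open.

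Gene models were missing from libraries in blocks. Of the 185354 absences, 81.6% concerned gene models with a median of 20 or more calls where they were listed, which argues against chance absence at low depth. The share of such gene models among all was not computed. Calls on the same read are not independent, so 20 calls can come from fewer reads. Whole sequences of the assembly missing from a library is a candidate explanation. Of 700 gene models with 2 positions, 561 (80.1%) had the lower position in exactly the libraries of a pattern of 20 or more other gene models, against at most 6 in 100 shuffles of the libraries. The shuffles stand for random sets of libraries only. Loss in other blocks could give the same match, so it does not single out whole sequences. Whether the blocks were lost in sequencing or in the processing stays open, and no biological explanation was tested.

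Most small p-values of the quasi-binomial regression went with lower salinity means, 51 of 57 (89.5%), against 54 of 76 with the block of title bands and 11 of 17 with edgeR. With limma it was 41 of 72, which can include differences in coverage at gene models without methylated calls. In the regression the unequal group sizes may account for the excess of lower means. Of 99 other splits into 3 and 12, 35 gave as large a share with the lower mean in the group of 12 (median 86.5%). Chance cannot be excluded for the 57 of 1900 (3.00%), as 34 of 100 splits, the real one included, gave as large a share of the gene models they tested (highest other 4.55%) and 70 of 100 as many by number (highest other 132), with 1520 to 3067 gene models tested in the others. With 0 that passed, 100 of 100 splits give as many by construction, which says nothing about chance; 20 of the others gave any, at most 6. A treatment effect too small or too rare for these libraries stays open.

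Control libraries did not stand out as a group in which gene models were methylated. The correlation of methylated state was 0.291 between controls, 0.287 between control and salinity libraries and 0.273 between salinity libraries (one-sided exact permutation p = 0.442). For each pair of libraries, the gene models listed in both were taken as a percentage of those listed in either. The mean of this percentage was 38.9% for libraries of the same title band and 35.6% for different bands (one-sided permutation p = 0.0567). It was 47.1%, 37.2% and 32.4% within the bands 1 to 5, 10 to 14 and 17 to 21.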
